A study of Homo sapiens with 12 samples.

How the data were processed

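RNA was extracted with Trizol from 22Rv1 cells exposed for 24 h to vehicle, enzalutamide, an autophagy-activating ligand or a degrader. Each of the 4 groups had 3 biologically independent replicates, and the 12 libraries were made with a stranded, poly(A)-selecting mRNA kit. The labels gave no doses.

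Per the submitters' processing notes, reads were aligned with HISAT2 to GRCh37 and assembled with StringTie; versions were not given. The authors deposited a gene table that holds, per the file headers, a read count and an FPKM value for each gene and library. The read count columns held whole numbers without any normalization, and every gene listed had at least 1 read in each library, so genes at 0 in any library are absent from the table. FPKM values, which the authors scaled to transcript length and library size, were used here solely to estimate gene length. The table also held, for each compound against vehicle, a deposited score, a signed linear fold change in which a fall is written as minus the inverse ratio. A deposited p-value column gave the authors' Benjamini-Hochberg adjusted p for each compound against vehicle, blank for some genes. The test behind these p-values was not named in the notes. A reference annotation on GRCh38 was used for gene names and older symbols, and no coordinates were taken from it.

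Library totals ran from 55.5 to 77.2 M counted reads. Counting error is small at this depth for most genes, and the chi-square per degree of freedom between replicates of a group was 5.56 to 22.8, so the spread between replicates set the precision. The p-values measure spread between libraries of a group.

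Of 18668 genes listed, 17702 were kept by edgeR filterByExpr (minimum count 10, minimum total count 15) and 966 were left out. Counts were scaled by trimmed mean of M values (TMM), with factors from 0.987 to 1.016. A quasi-likelihood negative binomial model with robust dispersion was fitted to all 12 libraries with group as the term, which left 8 residual degrees of freedom per gene, and 5 contrasts were tested with glmQLFTest. The contrasts were each compound against vehicle, and the degrader against enzalutamide and against the ligand. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum, and calls at an absolute log2 fold change of 1 or more were also counted. Levels are CPM (edgeR cpm with TMM-scaled library sizes), given as mean ± SD over 3 libraries; fold changes are log2 with their SE and 95% confidence interval. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8).

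The 24 gene lists (593 symbols) included glucocorticoid receptor targets, cholesterol synthesis, fatty acid synthesis, autophagy, lysosome, unfolded protein response, integrated stress response, NRF2 targets, heat shock, S phase, G2/M, p53 targets, BCL2 family, AhR and PXR targets, hypoxia and glycolysis, growth factor early response, interferon response, ribosome biogenesis, neuroendocrine markers, luminal markers, and basal and stromal markers. Lists were tested with limma camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the 24 lists within a comparison, and again with an estimated correlation. The directional fry test of limma was run beside camera. Counts of changed members are given after adjustment over all genes and after adjustment over the list alone.

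The genes named were fixed ones, among them KLK3, KLK2, TMPRSS2, FKBP5, UBE2C and SQSTM1, then the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group and no overlap between replicates, excluding uncharacterised and small RNA symbols. The rule added up to 4 members with the smallest p of each list that passed camera, and of the autophagy list in every comparison. Some genes and lists fixed in this way are not reported here. The lists, this rule, the tests and the alternatives were fixed before the data were examined. Other genes named, chiefly the changed members of a list with 5 or fewer of them in a direction, were chosen after their values were seen.

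Fold changes against vehicle share the 3 vehicle libraries, and 3 controls cannot be divided into separate sets. Covariances of fold changes across genes were therefore set beside 100 draws of simulated unchanged groups that share their controls, and overlaps of calls beside the product of both list sizes over the number of genes tested.

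The model was tested on simulated data of the same depths and dispersions with 200 changed genes per comparison, 100 at each fold, drawn from genes with a mean count of at least 50. At a 1.5-fold change it recovered 87 of 100 for degrader against vehicle (17633 genes), 82 for enzalutamide against vehicle (17616 genes), 82 for ligand against vehicle (17623 genes), 82 for degrader against enzalutamide (17629 genes) and 88 for degrader against ligand (17618 genes). At a 2-fold change it recovered 96, 96, 97, 97 and 97 of 100 in that order. Over both folds together there were 12, 12, 13, 16 and 10 false calls, a share of 5.13% to 8.21% of all calls and so above the nominal 5%, and 0 calls of the wrong sign.

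Alternatives were relative log expression (RLE) factors, no filter, a stricter filter (50 counts in 3 libraries), DESeq2, limma-voom, a fit of 6 libraries, the replicate number as a block, each library left out, an adjusted p under 0.01, a prior count of 0.5, an estimated correlation and fry. Leaving out the first replicate of every group, and setting the ligand against enzalutamide for the covariance, were added after seeing the data. The authors' own calls were counted beside those of edgeR.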

Results

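Gene expression was measured by sequencing of polyadenylated RNA in 22Rv1, a line of castration-resistant prostate cancer cells. Cells were exposed for 24 h to vehicle, to enzalutamide, a drug used in the clinic, to an autophagy-activating ligand, or to a degrader, with 3 libraries in each of the 4 groups. Library totals were 60.2 to 74.8 M counted reads with vehicle, 59.4 to 69.3 M with enzalutamide, 55.5 to 71.8 M with the ligand and 58.3 to 77.2 M with the degrader. Mitochondrially encoded genes took 8.22 ± 0.152% of the reads with vehicle, 8.13 ± 0.195% with enzalutamide, 8.34 ± 0.0551% with the ligand and 8.80 ± 0.346% with the degrader (mean ± SD, n = 3). The first principal component, with 31.6% of the variance, placed the 3 degrader libraries at 30.3 to 34.3 and the other libraries at -15.7 to -4.4. The second held 11% of it and placed replicates of the same group apart, for example vehicle at 5.2, -9.8 and -17.1.

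**Figure D1:**
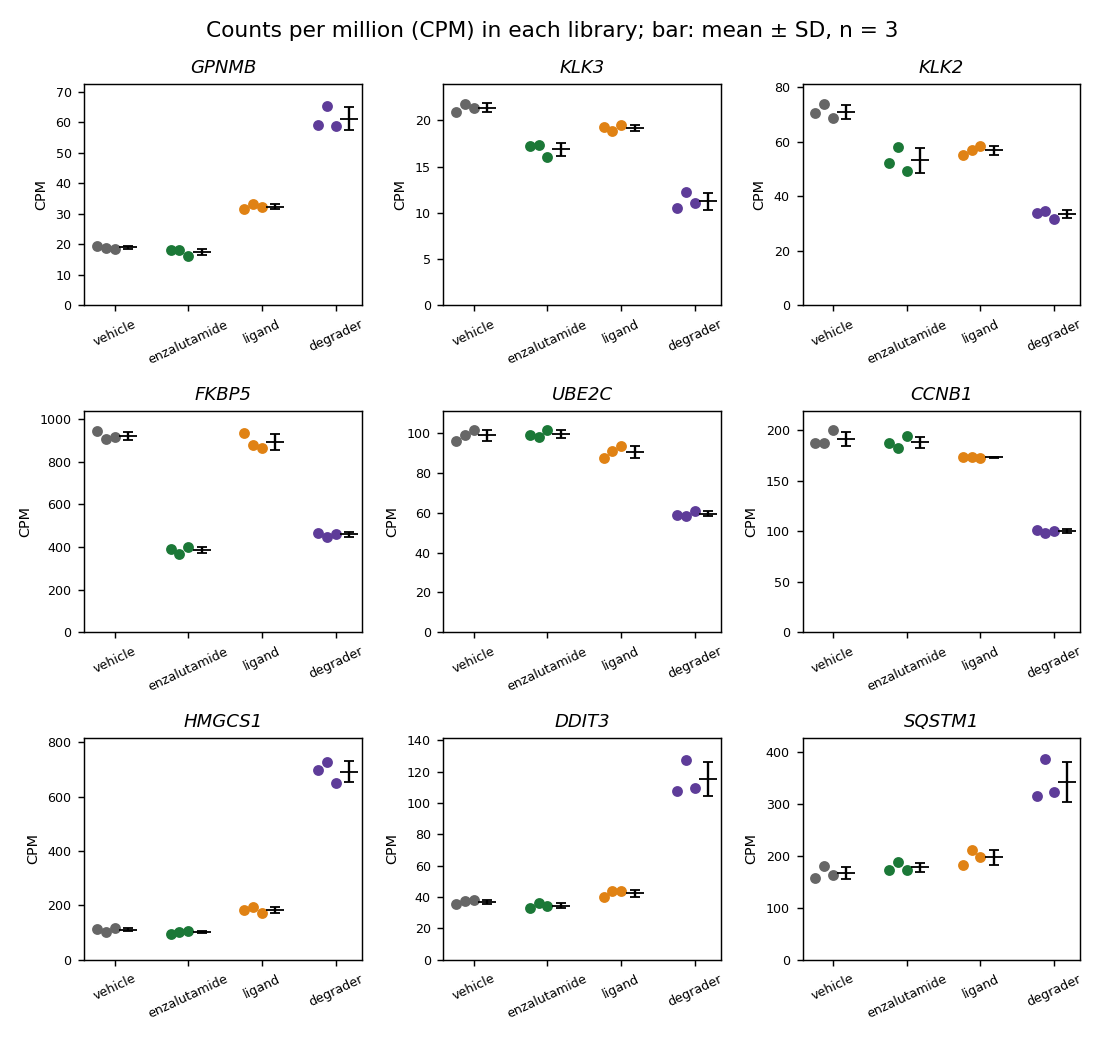
CPM of 9 genes in each of the 12 libraries (points), with the mean and SD of each group of 3 (bars); every vertical axis starts at 0. FKBP5 averaged 386.8 CPM with enzalutamide and 459.5 with the degrader against 921.8 with vehicle, and HMGCS1 averaged 692 CPM with the degrader against 110.1 with vehicle.

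The first comparison, degrader against vehicle, asked how exposure to the degrader altered transcript levels. Mitotic genes and the prostate genes KLK3 and KLK2 were lower in degrader-treated cells, and genes of sterol synthesis and of the integrated stress response were higher. FKBP5, a co-chaperone gene, fell from 921.8 ± 18.7 to 459.5 ± 10.3 CPM (log2 fold change -1.0, SE 0.05, adjusted p = 1.1e-10), and CCNB1, the mitotic cyclin B1, fell from 191.7 ± 7.22 to 100.4 ± 1.49 CPM (-0.93, SE 0.04, 1.19e-10). HMGCS1, a cytosolic enzyme at the start of the mevalonate pathway, rose from 110.1 ± 6.75 to 692 ± 38.4 CPM (2.65, SE 0.06, 7.43e-14), and DDIT3, the stress-induced transcription factor CHOP, rose from 36.9 ± 1.14 to 115.1 ± 10.8 CPM (1.64, SE 0.07, 2.52e-11; each mean ± SD, n = 3). By edgeR, 5795 of 17702 genes changed, 2898 higher and 2897 lower, with a median absolute log2 fold change of 0.33. At an absolute log2 fold change of 1 or more, 205 were higher and 115 lower.

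KLK3, which encodes prostate-specific antigen, fell by 0.92 (SE 0.07, adjusted p = 2.54e-08) from 21.4 ± 0.466 to 11.2 ± 0.908 CPM, and the related protease gene KLK2 fell by 1.09 (SE 0.06, 1.7e-09) from 71 ± 2.73 to 33.5 ± 1.48 CPM. ZBTB16, a zinc-finger transcription factor, fell by 0.67. TMPRSS2, the protease gene of prostate gene fusions, had a log2 fold change of -0.11 (95% confidence interval -0.21 to 0, adjusted p = 0.113). Of 15 luminal markers, 8 fell, also when adjusted over the list alone, where 2 were higher (median -0.23, limma camera adjusted p = 0.00237). They included the keratins KRT8 (-0.75) and KRT19 (-0.61), the homeobox gene HOXB13 (-0.32) and the membrane protein gene STEAP1 (-0.49).

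Mitotic (G2/M) genes fell in 39 of 40 cases, also when adjusted over the list alone (median -0.65, camera 7.9e-37). PLK1, a mitotic kinase, fell by 0.98 (SE 0.05, 5.42e-10), and KIF20A, a kinesin of cytokinesis, fell by 0.88. UBE2C, a ubiquitin-conjugating enzyme of the anaphase, fell by 0.73 (SE 0.04, 3.78e-09), CDC20, an activator of the anaphase-promoting complex, by 0.87, and BIRC5, which encodes survivin, by 0.82. The remaining member, the kinesin gene KIF20B, was at -0.24 (adjusted p = 0.174), and at -0.39 (0.0201) without vehicle replicate 1. S phase genes fell in 29 of 35 cases, or 31 when adjusted over the list alone (median -0.34, 1.82e-17). They included TYMS, the thymidylate synthase gene (-0.64), the ribonucleotide reductase subunits RRM1 (-0.51) and RRM2 (-0.47), and the helicase subunit MCM4 (-0.40). Ribosome biogenesis genes fell in 21 of 28 cases, or 23 when adjusted over the list alone (median -0.24, 3.75e-10). NCL, which encodes nucleolin, fell by 0.44, the nucleolar genes NOP56 and NOP2 fell by 0.43 and 0.34, and BOP1, needed for large ribosomal subunits, fell by 0.56.

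Sterol synthesis genes rose in 24 of 25 cases, also when adjusted over the list alone (median 1.29, camera 1.31e-32). INSIG1, a sterol sensor of the endoplasmic reticulum, rose by 2.50 (SE 0.06, 7.43e-14) from 40.3 ± 0.433 to 227.8 ± 14.3 CPM, and SQLE, the squalene epoxidase gene, by 1.92. The kinase gene PMVK was the exception, at 0.04 (adjusted p = 0.752). Fatty acid synthesis genes rose in 13 of 14 cases, also when adjusted over the list alone (median 0.61, 1.08e-10). They included SCD, the stearoyl-CoA desaturase gene (1.72, from 355.4 ± 15.2 to 1170.7 ± 70.4 CPM), FADS2 (0.95), FADS1 (0.60) and ACSL1 (0.71), while the elongase gene ELOVL5 fell by 0.31.

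Integrated stress response genes, targets of ATF4, rose in 26 of 29 cases, or 27 when adjusted over the list alone (median 0.90, camera 3.3e-27). SESN2, an inhibitor of mTORC1 signalling, rose by 1.54, the pseudokinase gene TRIB3 by 1.43, the glycine transporter gene SLC6A9 by 1.59 and SLC3A2, a subunit of amino acid transporters, by 0.94. Unfolded protein response genes rose in 12 of 20 cases, also when adjusted over the list alone (median 0.26, 6.76e-06). HERPUD1, a factor of degradation at the endoplasmic reticulum, rose by 0.82, SEC24D, a coat protein of secretory vesicles, by 0.73, the chaperone gene HYOU1 by 0.52 and SEL1L by 0.67. Heat shock genes fell in 12 of 18 cases, also when adjusted over the list alone (median -0.27, 4.51e-06), among them the cytosolic chaperone genes HSP90AA1 (-0.51), HSP90AB1 (-0.38), DNAJA1 (-0.35) and STIP1 (-0.37). Of 21 NRF2 targets, 10 rose and 5 fell, or 12 and 5 when adjusted over the list alone (median 0.17, 0.0132; adjusted p = 0.297 with an estimated correlation). Rises included HMOX1, the heme oxygenase gene (1.09), and the ferritin genes FTH1 (0.65) and FTL (0.62). The falls were TXN (-0.39), PRDX1 (-0.32), GCLC (-0.23), TALDO1 (-0.20) and AKR1C3 (-0.14), genes of redox enzymes and of the pentose phosphate pathway. The AKR1C3 call had an adjusted p of 0.175 without vehicle replicate 1, 0.0712 without vehicle replicate 2, and 0.0802, 0.0769 and 0.104 without degrader replicates 1, 2 and 3.

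Autophagy genes rose in 14 of 35 cases, or 15 when adjusted over the list alone with 1 lower (median 0.09, camera 0.000217; adjusted p = 0.118 with an estimated correlation). SQSTM1, which encodes the cargo receptor p62, rose by 1.04 (SE 0.08, 6.13e-08) from 167 ± 12.2 to 343.1 ± 39.3 CPM, and MAP1LC3B (0.76), GABARAPL1 (0.84) and WIPI1 (0.85), genes of the autophagosome membrane, rose too. Lysosomal genes rose in 23 of 38 cases, or 24 when adjusted over the list alone (median 0.23, 7.61e-08; adjusted p = 0.0679 with an estimated correlation). They included GPNMB, a glycoprotein of lysosomes and melanosomes (1.69), the sialidase gene NEU1 (1.35), FLCN, a regulator of TFE3 signalling (0.85), and the peptidase gene TPP1 (0.51). The cathepsin gene CTSB fell by 0.59, the galactosidase gene GLA by 0.38 and the transcription factor gene TFEB by 0.23. TFEB's call was lost without vehicle replicate 1 (0.101), vehicle replicate 3 (0.114), degrader replicate 2 (0.121) or degrader replicate 3 (0.0725).

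Hypoxia and glycolysis genes fell in 11 of 26 cases, or 14 when adjusted over the list alone (median -0.44, camera 4.69e-06; adjusted p = 0.381 with an estimated correlation). The glycolytic enzyme genes PGAM1 (-0.65), TPI1 (-0.55), GPI (-0.46) and PFKP (-0.44) were among them. The mean of this list was 6.67 ± 0.25 log2 CPM with vehicle, 6.33 ± 0.25 with enzalutamide, 6.39 ± 0.25 with the ligand and 6.24 ± 0.21 with the degrader (mean ± SD, n = 3). Replicate 1 was the highest of each group, at 6.93, 6.60, 6.62 and 6.48 in that order. With the degrader against enzalutamide the list's median was -0.13 and camera did not pass (0.0806). Against the ligand the median was -0.21 (camera 0.019, and 0.637 with an estimated correlation). High levels in the vehicle libraries thus stay open as a part of the fall and were not tested.

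The other lists did not pass camera. With 32.7% of all genes called in this comparison, called members alone do not set such a list apart. Of 26 p53 targets, 8 rose and 5 fell, or 9 and 5 when adjusted over the list alone (0.0705); the falls were POLH (-0.39), DDB2 (-0.32), CYFIP2 (-0.23), TRIAP1 (-0.19) and AEN (-0.16), genes of DNA repair and apoptosis among others. TRIAP1 was at 0.0542 without vehicle replicate 1, and AEN at 0.0993, 0.0696, 0.114 and 0.0941 without vehicle replicates 1 and 2 and degrader replicates 2 and 3. Among 12 AhR and PXR targets, the xenobiotic-induced genes CYP1A1 (2.47), CYP1A2 (2.22) and TIPARP (0.36) rose and UGT1A1 fell by 0.53, also when adjusted over the list alone (0.145). Glucocorticoid receptor targets rose in 6 of 14 cases, also when adjusted over the list alone (0.773), led by the glucocorticoid-induced leucine zipper gene TSC22D3 (0.77), and 4 fell, or 5 when adjusted over the list alone. These were FKBP5, ZBTB16, KLF9 (-0.48) and ERRFI1 (-0.19), a feedback inhibitor of the EGF receptor whose adjusted p was 0.0511 without degrader replicate 2. Of 11 neuroendocrine markers, the enolase gene ENO2, which the glycolysis list also holds, fell by 0.31, also when adjusted over the list alone (0.492; list median 0.02, mean -0.04).

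Of 16 BCL2 family genes, 5 rose and 2 fell, or 6 and 3 when adjusted over the list alone (0.279). The pro-apoptotic genes BMF (1.16), HRK (1.75), BBC3 (0.76) and BCL2L11 (0.21) and the anti-apoptotic BCL2L2 (0.32) rose, and BCL2L12 (-0.39) and BAK1 (-0.18) fell. BCL2L11 was at 0.0892, 0.0518 and 0.0756 without vehicle replicate 1 and degrader replicates 1 and 2. BAK1 was at 0.176 and 0.0878 without vehicle replicates 1 and 2, and at 0.0855, 0.0698 and 0.138 without degrader replicates 1, 2 and 3. Growth factor early response genes rose in 4 of 25 cases and fell in 8, or 4 and 9 when adjusted over the list alone (0.386), the rises being DUSP4 (0.75), ATF3 (0.95), CCND1 (0.24) and DUSP1 (0.38). Interferon response genes rose in 5 of 29 cases and fell in 7, or 5 and 8 when adjusted over the list alone (0.525). The rises were ISG20 (0.79), MX1 (0.54), STAT2 (0.23), IRF7 (0.66) and RSAD2 (0.37), whose adjusted p was 0.11, 0.0601, 0.0715 and 0.103 without vehicle replicates 1 and 2 and degrader replicates 2 and 3.

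Basal and stromal markers, which cover cell types other than luminal tumour cells, rose in 4 of 14 cases and fell in 2, or 4 and 3 when adjusted over the list alone (0.521). Rises were CDH2 (0.31), TAGLN (0.32), KRT15 (0.50) and ITGA6 (0.33), and falls were FN1, the fibronectin gene (-0.54), and CD44 (-0.13). All of these calls but that of FN1 were lost without some libraries. Without vehicle replicates 1, 2 and 3, adjusted p of the lost calls was 0.0675 and 0.0557 (replicates 1 and 2) for CDH2, 0.058 and 0.0959 (2 and 3) for TAGLN, 0.076 and 0.0565 (1 and 2) for KRT15, 0.138 and 0.0984 (1 and 2) for ITGA6, and 0.118 and 0.0756 (2 and 3) for CD44. Without degrader replicates it was 0.0519 and 0.0879 (2 and 3) for CDH2, 0.0953 and 0.0707 (1 and 2) for TAGLN, 0.117 (1) for KRT15, 0.0766 and 0.206 (1 and 2) for ITGA6, and 0.147 (2) for CD44.

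The largest rise was that of LAMP3, a lysosomal membrane protein gene, from 0.959 ± 0.335 to 27.5 ± 2.84 CPM (4.86, SE 0.16, 2.61e-12). NPHS1 (3.15), CALCA, which encodes calcitonin (3.0), SH3BGR (2.93), the mitochondrial dehydrogenase gene DMGDH (2.74), HMGCS1, INSIG1 and CYP1A1 followed. Large falls included the anion exchanger gene SLC26A3 (-1.70), the glucuronidation gene UGT1A3 (-1.34), PPP1R1B (-1.29), the thioredoxin inhibitor gene TXNIP (-1.27), KLK2 and the nicotinic receptor gene CHRNA2 (-1.10). Whether UGT1A3 and UGT1A1 shared reads was not examined. The remaining 2 of the 8 largest falls were read-through loci, SENP3-EIF4A1 (-3.35, SE 0.88, 0.0195) and BCL2L2-PABPN1 (-1.12, SE 0.38, 0.0473). SENP3-EIF4A1 lost its call without vehicle replicate 1 (0.0597), vehicle replicate 2 (0.0509), or degrader replicates 1, 2 or 3 (0.064, 0.0525, 0.0659), and BCL2L2-PABPN1 without vehicle replicates 1 or 3 (0.163, 0.0761) or degrader replicates 1 or 2 (0.0951, 0.0835). Of the lists above that passed camera, the calls of lysosome, hypoxia and glycolysis, autophagy and NRF2 targets were lost with an estimated correlation and the others held. Those that held did so at a much larger camera adjusted p. It was 0.0101 for G2/M, 0.008 for sterol synthesis, 0.00456 for the integrated stress response, 0.0208 for S phase and 0.0483 for heat shock. The authors' adjusted p was under 0.05 for 6001 genes, of which 5691 were also called by edgeR in the same direction.

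**Figure D2:**
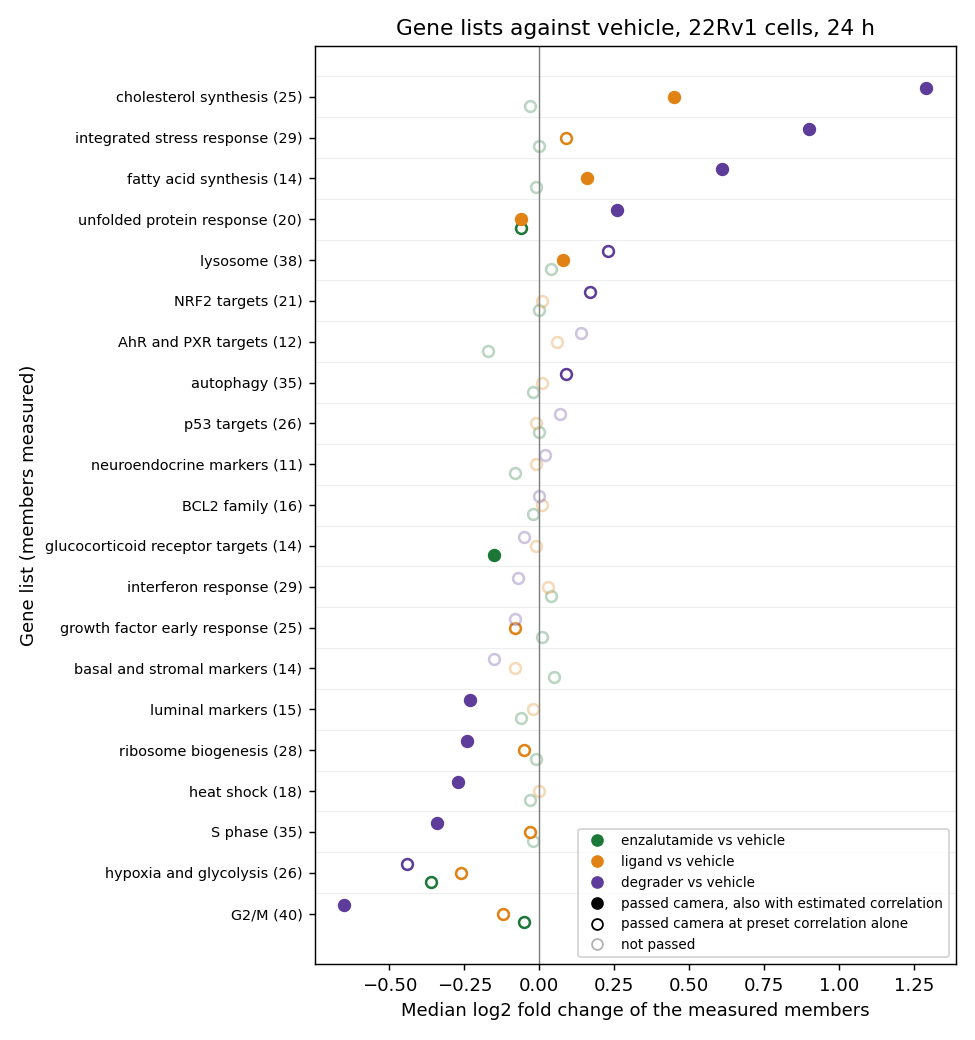
Median log2 fold change of 21 gene lists against vehicle, with the number of measured members in brackets; filled points passed camera also with an estimated correlation, open points with the preset correlation alone, and faint points did not pass. The degrader's medians run from -0.65 for G2/M to 1.29 for cholesterol synthesis.

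The second comparison, enzalutamide against vehicle, gave the response to a drug in clinical use in the same cells. Glucocorticoid receptor targets were lower as a list. FKBP5 fell from 921.8 ± 18.7 to 386.8 ± 15.2 CPM (-1.25, SE 0.05, edgeR adjusted p = 7.18e-11), SLC45A3, a solute carrier gene of luminal prostate cells, from 78.9 ± 5.63 to 36.4 ± 2.81 CPM (-1.12, SE 0.07, 3.99e-08), and KLK2 from 71 ± 2.73 to 53.2 ± 4.53 CPM (-0.42, SE 0.06, 0.000794; each mean ± SD, n = 3). KLK3 fell by 0.34 (SE 0.07, 0.00859), with an adjusted p of 0.0644 without enzalutamide replicate 2. Mitotic UBE2C had a log2 fold change of 0.01 (interval -0.08 to 0.11, 0.951), TMPRSS2 of -0.07 (-0.18 to 0.03, 0.674) and SQSTM1 of 0.09 (-0.07 to 0.25, 0.746). By edgeR, 255 of 17702 genes changed, 62 higher (32 to 45 with a library left out) and 193 lower (141 to 173), with a median absolute log2 fold change of 0.43; 22 were lower by 1 or more on the log2 scale, and 0 were higher by as much.

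Glucocorticoid receptor targets fell in 5 of 14 cases, or 6 when adjusted over the list alone (median -0.15, camera 8.03e-11), and this call held with an estimated correlation (0.00101). Besides FKBP5 these were ZBTB16 (-0.81), the transcription factor gene KLF9 (-0.62), ERRFI1 (-0.49) and the clock gene PER1 (-0.31). FKBP5 and ZBTB16 also belong to another of the lists fixed beforehand. The fall therefore does not single out the glucocorticoid receptor, whose activity was not measured. PER1 had an adjusted p of 0.142, 0.0532 and 0.151 without vehicle replicates 1, 2 and 3, and of 0.175 and 0.0578 without enzalutamide replicates 2 and 3.

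For 3 further lists camera passed and the call was lost with an estimated correlation. Hypoxia and glycolysis genes had a median of -0.36 (9.22e-10; adjusted p = 0.603 with an estimated correlation) with 0 of 26 genes passing, also when adjusted over the list alone, 5 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. PDK1 was at -0.48 (adjusted p = 0.289), ANKRD37 at -1.13 (0.353), HK2 at -0.23 (0.353) and P4HA1 at -0.47 (0.388), and the mean of the list by group is given with the degrader. With the replicate number as a block, edgeR called all of these genes (adjusted p = 0.00452, 0.00619, 0.00103 and 0.0147). In replicates 1, 2 and 3 the list mean was 6.93, 6.44 and 6.65 log2 CPM with vehicle. With enzalutamide it was 6.6, 6.11 and 6.28, lower in each same-numbered library. So it was with the ligand (6.62, 6.12 and 6.42) and the degrader (6.48, 6.11 and 6.14). High levels in the vehicle libraries therefore stay open as a part of this fall too. Of 20 unfolded protein response genes, the chaperone gene HSP90B1 fell by 0.20 (0.0264), and 2 were lower when adjusted over the list alone (median -0.06, 0.00116; adjusted p = 0.0938 with an estimated correlation). HSP90B1 was at 0.094, 0.123 and 0.0612 without vehicle replicates 1, 2 and 3, and at 0.109 and 0.145 without enzalutamide replicates 1 and 3. PDIA4, HSPA5 and MANF, further chaperone genes, had log2 fold changes of -0.13 each. PDIA4 (0.0229) and HSPA5 (0.042) passed edgeR with the replicate number as a block. G2/M genes had a median of -0.05 (0.00221; adjusted p = 0.812 with an estimated correlation), with 0 of 40 passing, also when adjusted over the list alone, 3 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom. CKAP2 was at -0.22 (0.0912, and 0.00292 with the block), TTK at -0.17, HMMR at -0.14 and HJURP at -0.09. The list had an adjusted p of 0.0936 without vehicle replicate 2 and 0.192 without enzalutamide replicate 1.

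Lists that did not pass held several called genes. Of 15 luminal markers, the transcription factor gene GATA2 rose by 0.32 and STEAP1 and STEAP2 fell by 0.68 and 0.58, with 4 higher and 4 lower when adjusted over the list alone (0.361); STEAP2 was at 0.0744 without enzalutamide replicate 1. Of 21 NRF2 targets, the aldo-keto reductase genes AKR1C2 (0.48), AKR1C1 (0.45) and AKR1C3 (0.28) rose and GCLC fell by 0.58, also when adjusted over the list alone (0.74); reads shared between these AKR1C paralogs were not examined. UGT1A1 fell by 0.52 among 12 AhR and PXR targets, also when adjusted over the list alone (0.361). Reads shared between UGT1A1 and UGT1A3, named below, were not examined. Of 14 fatty acid synthesis genes, SREBF1, the regulator of lipid synthesis, rose by 0.24 and ELOVL5 fell by 0.59, with 2 higher and 2 lower when adjusted over the list alone (0.566). SREBF1 was at 0.0913 and 0.106 without vehicle replicates 2 and 3 and at 0.0619 and 0.155 without enzalutamide replicates 1 and 3. Of 14 basal and stromal markers, CDH2 rose by 0.43 and FN1 (-0.45) and CD44 (-0.24) fell, also when adjusted over the list alone (median 0.05, mean -0.02, 0.533). CDH2 was at 0.123, 0.123 and 0.0899 without vehicle replicates 1, 2 and 3, and at 0.0833 and 0.24 without enzalutamide replicates 1 and 3.

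The antiproliferative gene BTG2 rose by 0.62 and the death receptor gene TNFRSF10B fell by 0.21 among 26 p53 targets, also when adjusted over the list alone (0.69). TNFRSF10B was at 0.0834, 0.099 and 0.143 without vehicle replicates 1, 2 and 3, and at 0.153 and 0.131 without enzalutamide replicates 1 and 2. PMAIP1, which encodes the pro-apoptotic protein NOXA, fell by 0.36 among 16 BCL2 family genes, with 1 higher and 1 lower when adjusted over the list alone (0.74). It was at 0.187, 0.097 and 0.0947 without vehicle replicates 1, 2 and 3, and at 0.122, 0.162 and 0.155 without enzalutamide replicates 1, 2 and 3.

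In the remaining lists edgeR called 0 members over all genes. These were lysosome (camera 0.159), autophagy (0.376), neuroendocrine markers (0.376), heat shock (0.389), S phase (0.389), integrated stress response (0.435), growth factor early response (0.69), interferon response (0.69), cholesterol synthesis (0.69) and ribosome biogenesis (0.69). Adjusted over the list alone they held 0 too, except for 1 higher growth factor gene. At an unadjusted p under 0.05 (higher and lower) there were 5 and 1 lysosomal, 1 and 2 autophagy, 0 and 2 neuroendocrine, 2 and 1 heat shock, 0 and 2 S phase, 0 and 2 integrated stress response, 5 and 0 growth factor, 2 and 1 interferon, 2 and 2 sterol synthesis and 0 and 0 ribosome biogenesis genes. DESeq2 called 1 lower integrated stress response gene and 1 higher growth factor gene and 0 in the others, and limma-voom called 0 in each. ATG4A (-0.15), RB1CC1 (-0.16), ATG2A (0.15) and BNIP3L (-0.44) had the smallest p of the autophagy list, at adjusted p = 0.457, 0.459, 0.464 and 0.574. The growth factor and interferon lists had medians of 0.01 and 0.04 and means of -0.03 and -0.04.

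The largest rises were those of BAMBI, a pseudoreceptor of TGF-beta signalling (0.91, SE 0.09, 8.63e-06), SOD3, an extracellular superoxide dismutase (0.91), the homeobox gene EVX1 (0.85), the protocadherin gene PCDH17 (0.71), SPOCK2 (0.64), BTG2, HOXA13 (0.62) and PCED1B (0.60). The largest falls besides FKBP5 and SLC45A3 were SLC26A3 (-1.97, SE 0.11, 3.71e-08), the amino acid transporter gene SLC38A4 (-1.40), the acyltransferase gene MBOAT2 (-1.36), the transcription factor gene MAF (-1.35), CHRNA2 (-1.18) and UGT1A3 (-1.07, 0.00939), whose adjusted p was 0.0634 and 0.0598 without enzalutamide replicates 2 and 3. The authors' adjusted p was under 0.05 for 388 genes, which included all 255 edgeR calls in the same direction.

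The third comparison, ligand against vehicle, gave the response to the autophagy-activating ligand. Sterol synthesis genes, fatty acid synthesis genes and some lysosomal genes were higher. INSIG1 rose from 40.3 ± 0.433 to 69.9 ± 5.55 CPM (0.79, SE 0.06, edgeR adjusted p = 5.28e-06), HMGCS1 from 110.1 ± 6.75 to 182.4 ± 11.9 CPM (0.73, SE 0.06, 5.28e-06) and GPNMB from 19 ± 0.399 to 32.2 ± 0.861 CPM (0.77, SE 0.06, 5.28e-06; each mean ± SD, n = 3). SQSTM1 had a log2 fold change of 0.24 (interval 0.08 to 0.41, adjusted p = 0.392), FKBP5 of -0.04 (-0.14 to 0.05, 0.91), KLK3 of -0.15 (-0.29 to -0.02, 0.616), TMPRSS2 of 0.07 (0.832) and UBE2C of -0.12 (-0.22 to -0.03, 0.519). With the replicate number as a block, SQSTM1 passed edgeR (adjusted p = 0.00157). By edgeR, 42 of 17702 genes changed, 36 higher and 6 lower, with a median absolute log2 fold change of 0.43. The count was 24 without vehicle replicate 2, 21 without vehicle replicate 3, 22 without ligand replicate 1, 25 without ligand replicate 2 and 77 without ligand replicate 3.

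Sterol synthesis genes rose in 17 of 25 cases, or 24 when adjusted over the list alone (median 0.45, camera 1.24e-63). SQLE rose by 0.72, MSMO1, a sterol demethylation enzyme, by 0.62 and STARD4, a sterol carrier, by 0.52 (0.0247). STARD4's call was lost without vehicle replicate 1 (0.113), vehicle replicate 2 (0.174) or ligand replicate 1 (0.148). Fatty acid synthesis genes rose in 4 of 14 cases, or 5 when adjusted over the list alone (median 0.16, 4.24e-14): SREBF1 (0.47), SCD (0.52) and the desaturase genes FADS1 (0.24) and FADS2 (0.35). FADS1 was at 0.0743, 0.0791 and 0.111 without vehicle replicates 1, 2 and 3 and at 0.135 without ligand replicate 1. FADS2 was at 0.0823 and 0.172 without vehicle replicates 2 and 3 and at 0.135 and 0.124 without ligand replicates 1 and 2. Lysosomal genes rose in 4 of 38 cases, or 10 when adjusted over the list alone (median 0.08, 1.03e-12): GPNMB, NEU1 (0.52), TPP1 (0.27) and FLCN (0.34). TPP1 was at 0.0576 without vehicle replicate 2, and FLCN at 0.092 and 0.0616 without vehicle replicate 3 and ligand replicate 2.

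Of 35 autophagy genes, edgeR called 0, also when adjusted over the list alone (camera 0.937). At an unadjusted p under 0.05, 3 were higher and 1 lower, and DESeq2 and limma-voom called 0. Its median was 0.01, its mean -0.01 and camera's direction up. NBR1 was at -0.12, MAP1LC3A at 0.19 and UVRAG at 0.17, with adjusted p = 0.469, 0.576 and 0.576. KLK2 fell from 71 ± 2.73 to 57 ± 1.67 CPM (-0.32, SE 0.06, 0.0331). KLK2's call was lost without any of the 6 libraries, with an adjusted p of 0.145, 0.101 and 0.152 without vehicle replicates 1, 2 and 3 and of 0.161, 0.0846 and 0.0771 without ligand replicates 1, 2 and 3. Unfolded protein response genes moved down as a list with 0 of 20 called, or 1 when adjusted over the list alone (median -0.06, 1.03e-05), 7 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom. HSP90B1 was at -0.19 (0.12, and 0.00953 with the replicate number as a block), HSPA5 at -0.14, XBP1 at -0.12 and PDIA4 at -0.10. The sterol, fatty acid, lysosome and unfolded protein response calls held with an estimated correlation, at a larger camera adjusted p (0.00216, 0.00079, 0.0454 and 0.0286).

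For 6 other lists that passed camera, edgeR called 0 members over all genes and the call was lost with an estimated correlation. G2/M genes had a median of -0.12 (6.04e-19; adjusted p = 0.0635 with an estimated correlation), 22 of 40 lower at an unadjusted p under 0.05, and 0 called when adjusted over the list alone, by DESeq2 or by limma-voom. CCNB1 was at -0.15 (0.29), the kinesin gene CENPE at -0.29 (0.294), BUB1B at -0.13 and NUSAP1 at -0.14. Hypoxia and glycolysis genes had a median of -0.26 (1.47e-10; adjusted p = 0.258 with an estimated correlation) and 5 lower at an unadjusted p under 0.05, with PGAM1 at -0.17, PDK1 at -0.41, ENO1 at -0.25 and EGLN3 at -0.57. With the replicate number as a block, edgeR called CENPE (0.0103), PGAM1 (0.0105), PDK1 (0.0314) and ENO1 (0.00135). The mean of the hypoxia and glycolysis list was below vehicle with every compound, so high vehicle levels stay open here too. Growth factor early response genes had a median of -0.08 and 3 lower when adjusted over the list alone, 8 at an unadjusted p under 0.05 (1.03e-05; adjusted p = 0.137 with an estimated correlation), with the immediate early genes IER3 and FOS at -0.48 each, ETV4 at -0.27 and DUSP5 at -0.65.

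Integrated stress response genes had a median of 0.09 and 5 higher when adjusted over the list alone (camera 1.32e-05; adjusted p = 0.152 with an estimated correlation). The serine synthesis gene PHGDH was at 0.25 (0.12), NUPR1 at 0.33 (0.263), ATF5 at 0.19 and ADM2 at 0.21, and without ligand replicate 3 PHGDH was at 0.32 (0.00582) and NUPR1 at 0.43 (0.0125). Both also passed edgeR with the replicate number as a block (0.00177 and 0.000525). Ribosome biogenesis genes had a median of -0.05 (0.00404; adjusted p = 0.194 with an estimated correlation, and 0.33 at the preset correlation without ligand replicate 3), with PPAN at -0.25, WDR43 at -0.10, TFB2M at -0.11 and NCL at -0.07. S phase genes had a median of -0.03 (0.0291; adjusted p = 0.49 with an estimated correlation), with RRM2 at -0.13, RRM1 and RFC2 at -0.09 and CCNE2 at -0.15. The S phase list was at 0.353 without vehicle replicate 2, 0.136 without ligand replicate 1 and 0.28 without ligand replicate 3. At an unadjusted p under 0.05, 12 of the stress response genes were higher and 2 of each of the last 2 lists lower, and DESeq2 called 2, 0 and 0 of them. DESeq2 also called 0 hypoxia and growth factor genes, and limma-voom 0 in each of these lists.

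Lists that did not pass were neuroendocrine markers (camera 0.184), luminal markers (0.211), AhR and PXR targets (0.261), NRF2 targets (0.399), interferon response (0.442), BCL2 family (0.442), basal and stromal markers (0.442; median -0.08, mean 0.03), heat shock (0.5), glucocorticoid receptor targets (0.719) and p53 targets (0.937). Over all genes edgeR called FN1 among 14 basal and stromal markers and 0 members of the others. Adjusted over the list alone, FN1 was lower, and 2 glucocorticoid receptor targets, 1 AhR and PXR target, 1 BCL2 family gene and 1 basal and stromal marker were higher. At an unadjusted p under 0.05 (higher and lower) the lists with 0 calls held 0 and 1 neuroendocrine, 0 and 1 luminal, 2 and 1 AhR and PXR, 2 and 0 NRF2, 2 and 0 interferon, 2 and 0 BCL2 family, 3 and 0 heat shock, 2 and 1 glucocorticoid and 1 and 0 p53 genes. DESeq2 called 2 higher glucocorticoid receptor targets and 1 higher AhR and PXR target among these and limma-voom 0. The glucocorticoid list had a median of -0.01 and a mean of 0.02, with camera pointing up.

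The falls were HLA-DMB, a class II antigen-loading gene (-0.43, SE 0.08, 0.0247), the arrestin genes ARRDC4 (-0.41, 0.00443) and TXNIP (-0.36, 0.00258), FN1 (-0.39, 0.00543), KLK2 and ABCG1, a sterol exporter gene (-0.88, 0.039). CDHR1, a cadherin gene, was the call of largest size (1.17, 0.0208). HLA-DMB was at 0.111, 0.111 and 0.0949 without vehicle replicates 1, 2 and 3 and at 0.16 and 0.074 without ligand replicates 2 and 3, and FN1 at 0.0523 and 0.0681 without vehicle replicate 3 and ligand replicate 1. ABCG1 was at 0.0952, 0.135 and 0.222 without vehicle replicates 1, 2 and 3 and at 0.246, 0.0806 and 0.0809 without ligand replicates 1, 2 and 3. CDHR1 was at 0.113, 0.0758 and 0.0949 without vehicle replicates 1, 2 and 3 and at 0.148 and 0.0657 without ligand replicates 1 and 2. The authors' adjusted p was under 0.05 for 124 genes, which included all 42 edgeR calls in the same direction.

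The degrader was also compared directly with enzalutamide. Mitotic genes were lower with the degrader, and sterol synthesis and stress response genes were higher. KLK2 was lower by 0.67 (SE 0.06, edgeR adjusted p = 4.94e-07; 33.5 ± 1.48 against 53.2 ± 4.53 CPM) and KLK3 was lower by 0.58 (SE 0.07, 5.72e-06; 11.2 ± 0.908 against 16.9 ± 0.714 CPM), while FKBP5 was higher by 0.25 (SE 0.04, 0.000451; 459.5 ± 10.3 against 386.8 ± 15.2 CPM; mean ± SD, n = 3). MAF (0.93) and SLC45A3 (0.71) were higher with the degrader as well. Glucocorticoid receptor targets were higher in 10 of 14 cases, or 11 when adjusted over the list alone (median 0.29, 9.16e-05), including TSC22D3 (0.73), the metallothionein gene MT2A (0.70), TFCP2L1 (0.43) and NR3C1, the receptor gene itself (0.47). GLUL, the glutamine synthetase gene, was lower (-0.11), a call lost without any of the 6 libraries (0.0781, 0.101 and 0.0776 without enzalutamide replicates 1, 2 and 3, and 0.0652, 0.139 and 0.0652 without degrader replicates 1, 2 and 3). Against vehicle the glucocorticoid list had a median of -0.05 with the degrader (camera 0.773) and of -0.15 with enzalutamide (camera 8.03e-11). The difference between both compounds therefore does not show a rise of this list with the degrader. TMPRSS2 differed by -0.03 (interval -0.14 to 0.07, 0.649).

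By edgeR, 5726 genes differed, 2880 higher and 2846 lower with the degrader than with enzalutamide. G2/M genes were lower in 39 of 40 cases (median -0.60, camera 2.46e-34), with UBE2C at -0.74 and PLK1 at -1.0. Sterol synthesis genes were higher in 24 of 25 cases (median 1.25, 3.3e-32) and fatty acid synthesis genes in 13 of 14 (median 0.59, 2.49e-13), with HMGCS1 at 2.79, INSIG1 at 2.64 and SCD at 1.80. These counts were the same when adjusted over the list alone. S phase genes were lower in 28 of 35 cases, or 29 when adjusted over the list alone (median -0.33, 3.07e-16), ribosome biogenesis genes in 21 of 28, or 22 (median -0.21, 1.05e-09), and unfolded protein response genes were higher in 14 of 20, or 14 (median 0.29, 5.5e-09). Integrated stress response genes were higher in 28 of 29 cases, or 28 when adjusted over the list alone (median 0.91, 5.99e-29), with DDIT3 at 1.74, and ATF5 was lower (-0.16). The ATF5 call was lost without enzalutamide replicates 1 or 3 (0.191, 0.0872) or degrader replicates 1, 2 or 3 (0.062, 0.149, 0.0883).

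Autophagy genes were higher with the degrader than with enzalutamide in 16 of 35 cases, or 17 when adjusted over the list alone (median 0.16, camera 1.91e-05; adjusted p = 0.0773 with an estimated correlation). SQSTM1 was at 0.95 (SE 0.08, 1.83e-07), WIPI1 at 0.92 and MAP1LC3B at 0.83. Among 12 AhR and PXR targets CYP1A2 (1.80), CYP1A1 (2.11), TIPARP (0.48) and CYP1B1 (0.43) were higher, or 5 genes when adjusted over the list alone (0.0139; adjusted p = 0.0542 with an estimated correlation). Calls that held with an estimated correlation were those of G2/M, cholesterol synthesis, fatty acid synthesis, integrated stress response, unfolded protein response, S phase, ribosome biogenesis and glucocorticoid receptor targets. Their camera adjusted p then ran from 0.00104 (fatty acid synthesis) to 0.0253 (S phase). Lost besides autophagy and AhR and PXR targets were lysosome (5.56e-06; adjusted p = 0.0968 with an estimated correlation), heat shock (1.62e-05; 0.0616), luminal markers (0.0377; 0.0773) and NRF2 targets (0.0377; 0.391). At the preset correlation luminal markers were at 0.0525 without enzalutamide replicate 2 and 0.0575 with the stricter filter. NRF2 targets were at 0.0561 with that filter and at 0.0564, 0.0848 and 0.071 without enzalutamide replicates 2 and 3 and degrader replicate 1. The largest differences included LAMP3 (5.05) and NIBAN1, a stress-induced gene (2.60), the read-through locus ARPIN-AP3S2 (-1.55), PPP1R1B (-1.23) and the cholecystokinin receptor gene CCKBR (-1.05).

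The degrader was compared with the ligand in the same way; the labels give no doses, so it is not known whether the concentrations matched. Mitotic genes and KLK2, KLK3 and FKBP5 were lower with the degrader than with the ligand, and sterol synthesis genes, which the ligand also raised, were higher still. FKBP5 was lower by 0.96 (SE 0.05, edgeR adjusted p = 3.64e-10; 459.5 ± 10.3 against 894.5 ± 37.7 CPM), and KLK2 and KLK3 each by a log2 fold change of -0.77 (1.53e-07 and 3.46e-07). HMGCS1 was higher by 1.92 (SE 0.06, 4.26e-12; 692 ± 38.4 against 182.4 ± 11.9 CPM; mean ± SD, n = 3), INSIG1 by 1.70, SQLE by 1.20, SCD by 1.20, GPNMB by 0.92 and SQSTM1 by 0.80 (SE 0.08, 1.69e-06). TMPRSS2 was at -0.18 (0.0124). By edgeR, 5049 genes differed, 2535 higher and 2514 lower.

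G2/M genes were lower with the degrader than with the ligand in 39 of 40 cases, also when adjusted over the list alone (median -0.56, camera 8.34e-36). Sterol synthesis genes were higher in 24 of 25 cases, also when adjusted over the list alone (median 0.75, 2.29e-27). Integrated stress response genes were higher in 27 of 29 cases, or 28 when adjusted over the list alone, with ATF5 lower (-0.26; list median 0.79, 5.87e-29). Autophagy genes were higher in 12 of 35 cases, or 14 when adjusted over the list alone (median 0.10, 2.72e-05; adjusted p = 0.0887 with an estimated correlation).

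Besides the calls of G2/M, sterol synthesis and integrated stress response, those that held with an estimated correlation were S phase (4.94e-18), unfolded protein response (2.82e-10), ribosome biogenesis (7.83e-09), fatty acid synthesis (3.35e-08), heat shock (3.35e-08) and luminal markers (0.00571). With that correlation the camera adjusted p of all these lists ran from 0.00277 (integrated stress response) to 0.0309 (luminal markers). Lysosomal genes (0.000237; adjusted p = 0.189 with an estimated correlation), hypoxia and glycolysis genes (0.019; 0.637), NRF2 targets (0.0215; 0.336) and p53 targets (0.0428; 0.0801) lost their call, as autophagy genes did. At the preset correlation hypoxia and glycolysis genes were at 0.171 and 0.0525 without ligand replicates 1 and 3 and at 0.0804 and 0.0727 without degrader replicates 2 and 3. NRF2 targets were at 0.0618 and 0.0526 without ligand replicate 3 and degrader replicate 1, and p53 targets at 0.0598 without ligand replicate 3 and 0.0567 with the stricter filter. The stress cytokine gene GDF15 (1.74) and the cystine transporter gene SLC7A11 (1.54) were higher with the degrader, and LAMP3 differed most (4.75, SE 0.16, 6.27e-12). The read-through loci CZ1P-ASNS (3.0), UBE2F-SCLY (2.40), SENP3-EIF4A1 (-3.54) and BUB1B-PAK6 (-2.83) were also called. CZ1P-ASNS was at 0.0614 and 0.0571 without ligand replicate 1 and degrader replicate 2, and UBE2F-SCLY at 0.0533, 0.116 and 0.0948 without ligand replicates 1, 2 and 3 and at 0.0903, 0.126 and 0.067 without degrader replicates 1, 2 and 3. SENP3-EIF4A1 was at 0.0509 without ligand replicate 2 and at 0.0583, 0.0506 and 0.0629 without degrader replicates 1, 2 and 3, and BUB1B-PAK6 at 0.143 and 0.0542 without ligand replicates 1 and 3 and at 0.0929, 0.118 and 0.125 without degrader replicates 1, 2 and 3.

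**Figure D3:**
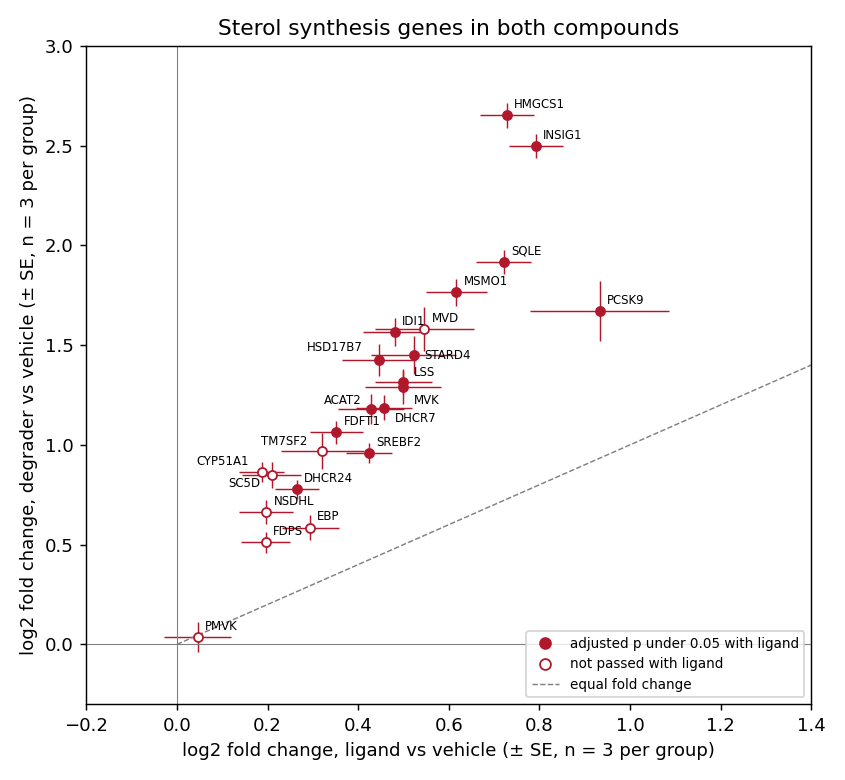
Log2 fold change against vehicle of 23 sterol synthesis genes with the ligand (horizontal axis) and the degrader (vertical axis), with SE bars (n = 3 per group, shared vehicle libraries) and a dashed line at equal fold change. HMGCS1 was at 0.73 and 2.65, INSIG1 at 0.79 and 2.50, and PMVK, at 0.04 with the degrader, passed in neither.

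The calls against vehicle overlapped. All 36 genes higher with the ligand were higher with the degrader, where 5.89 would be shared by independent lists, and all 6 lower genes were lower (0.982 by independent lists); their median log2 fold changes were 0.44 and -0.40 with the ligand and 1.15 and -1.0 with the degrader. Of 193 genes lower with enzalutamide, 133 were lower with the degrader (31.6 by independent lists), 17 higher and 43 not called, with medians of -0.45 and -0.35. Of the 62 higher genes, 28 were higher with the degrader (10.2 by independent lists), 7 lower and 27 not called. Enzalutamide and the ligand shared 1 higher gene and 2 lower genes, against 0.126 and 0.0654 by independent lists. Across all 17702 genes, which are not independent replicates, the covariance of log2 fold changes was 0.0254 for degrader and enzalutamide (0.016 for simulated unchanged groups sharing their controls), 0.0308 for degrader and ligand (0.0159) and 0.0191 for enzalutamide and ligand (0.0159). The corresponding r was 0.33, 0.45 and 0.46, against 0.50, 0.50 and 0.49 in the simulations. Each pair of fold changes shares the same 3 vehicle libraries, which raises overlap and covariance, and 3 controls are too few to split. The covariance lay above the highest of 100 simulations in each pair (0.019, 0.0183 and 0.0179). The simulations drew each gene independently, so their spread leaves out genes that vary together between libraries. Exceeding them therefore does not show a shared response. The covariance of enzalutamide and ligand was 0.0106 with a stricter filter (0.0083 simulated). It was 0.0275 to 0.0289 with a vehicle library left out (0.024 to 0.0249 simulated). Shares of genes with the same sign were 57.6%, 64.1% and 68.9% in the order of the pairs, against 66.7%, 66.8% and 66.6% on average in the simulations. For the overlaps the part due to shared controls was not estimated.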

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

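Of the alternatives described here, leaving out the first replicate of all 4 groups together (8 libraries) and setting the ligand against enzalutamide for the covariance were chosen after the result was seen. Counts of genes were within 1.5 times the reported count in 58 of 80 alternatives, lower in 17 and higher in 5. For degrader against vehicle (5795), an adjusted p under 0.01 left 3791 genes and a log2 fold change of 1 or more left 320; for degrader against enzalutamide (5726) these were 3655 and 279, and for degrader against ligand (5049) 3067 and 217, fewer because the thresholds are stricter. For enzalutamide against vehicle (255), 163 passed at 0.01 and 22 at the fold minimum, 136 with 8 libraries, 403 by DESeq2 and 553 with the replicate number as a block. For ligand against vehicle (42), 23 passed at 0.01 and 1 at the fold minimum, 23 with 8 libraries, 25 with the 6 libraries of the 2 groups, 121 by DESeq2 and 191 with the block. The thresholds are stricter here too; the cause of the other changes was not tested. With the block 125 genes were higher and 66 lower with the ligand, and the counts were 7265 for degrader against vehicle, 7221 against enzalutamide and 6559 against ligand. The labels do not say that a replicate number marks a shared batch or day. The r of residuals was -0.03 to 0.21 for the 18 pairs sharing a number, with 7 above 0.1, and -0.17 to 0.07 for the 36 other pairs, and 11 of 12 libraries had their highest r with a library of another group that shared their number. This points to same-numbered libraries varying together, a reading from the data and not from the design. The fit without a block was kept because it was fixed beforehand. Pairs with a lower r do not argue against a block. The enzalutamide and ligand counts depend on this choice (553 and 191 with the block). Of the named genes that had not passed, 7 passed with the block for enzalutamide: PDK1 (adjusted p = 0.00452), ANKRD37 (0.00619), HK2 (0.00103), P4HA1 (0.0147), PDIA4 (0.0229), HSPA5 (0.042) and CKAP2 (0.00292). For the ligand 10 did, among them SQSTM1 (0.00157), NUPR1 (0.000525), ENO1 (0.00135), PHGDH (0.00177), HSP90B1 (0.00953), CENPE (0.0103), PGAM1 (0.0105) and PDK1 (0.0314). KIF20B (0.037) passed with it for degrader against vehicle. With each library left out, the counts were 4580 to 5217 for degrader against vehicle, 173 to 218 for enzalutamide, 21 to 77 for the ligand, 4531 to 5210 for degrader against enzalutamide and 3781 to 5408 for degrader against ligand. The ligand count was 21 without vehicle replicate 3 and 77 without ligand replicate 3. Counts of lists, over all 24, were within 1.5 times in 60 of 65 alternatives. An estimated correlation left 11 of 16 lists for degrader against vehicle and against ligand and 9 of 16 for degrader against enzalutamide. It left 2 of 5 for enzalutamide and 5 of 11 for the ligand. The fry test passed 8 and 7 lists for enzalutamide and the ligand, of which 3 and 6 had passed camera. With enzalutamide it did not pass hypoxia and glycolysis (0.353) or G2/M (0.397). With the ligand it passed G2/M (0.0278) but not hypoxia and glycolysis (0.264), growth factor early response (0.0651), integrated stress response (0.0895), ribosome biogenesis (0.0895) or S phase (0.36). Leaving out a library gave 15 to 17, 4 to 5, 9 to 12, 14 to 16 and 13 to 16 lists in the order of the gene counts. Of 897 tests of single lists, 826 were the same, and 6 were reversed. These were all autophagy with the ligand, which had not passed (0.937): its direction was down at an adjusted p of 0.986 with the block, 0.992 with 8 libraries, 0.991 by fry, 0.823 and 0.848 without vehicle replicates 2 and 3, and 0.384 without ligand replicate 1, and over each library left out the adjusted p ran from 0.369 to 0.848. Covariances with the stricter filter were 0.0171 for degrader and enzalutamide, 0.0218 for degrader and ligand and 0.0106 for enzalutamide and ligand, with simulated values of 0.00806, 0.00812 and 0.0083. With a vehicle library left out they were 0.0332 to 0.0361, 0.0387 to 0.0416 and 0.0275 to 0.0289, higher since fewer controls are shared. The covariance of degrader and ligand was 0.0054 with the ligand set against enzalutamide, which removes the shared vehicle libraries and also subtracts the enzalutamide response. Of 3123 tests of the named genes, 3028 were the same, and 2 were reversed. UBE2C with enzalutamide, which had not passed (0.01), was at -0.01 without vehicle replicate 3 and 0 without enzalutamide replicate 2, within -0.01 to 0.03 over each library left out. Of 1449 tests of genes named outside the rule, 1226 were the same. Counting error at this depth limits little here, since replicate spread exceeded it, but genes at 0 in any library are absent from the table.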

Other observations

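The 5 gene lists in this paragraph, and the tests of sterol levels in the vehicle libraries and of gene length below, were chosen only after the result was seen. With the degrader, 7 of 7 metallothionein genes were higher, also when adjusted over the list alone (median log2 fold change 1.58, limma camera adjusted p = 8.41e-09; adjusted p = 0.0749 with an estimated correlation); reads shared between these paralogs were not examined. Among 20 cytosolic aminoacyl-tRNA synthetase genes, many of them ATF4 targets, 11 were higher and 5 lower, also when adjusted over the list alone (median 0.24, 0.00178; adjusted p = 0.0749 with an estimated correlation). The lower ones were VARS1 (-0.38), FARSA (-0.31), FARSB (-0.27), KARS1 (-0.25) and RARS1 (-0.23). Nuclear genes of the respiratory chain were lower in 26 of 30 cases, or 29 when adjusted over the list alone (median -0.25, 2.81e-12; adjusted p = 0.104 with an estimated correlation), and proteasome genes in 22 of 32, or 23 (median -0.18, 8.41e-09; adjusted p = 0.144 with an estimated correlation). Of 13 mitochondrially encoded genes, ND1 (0.34) and COX1 (0.18) were higher (list 0.362; adjusted p = 0.732 with an estimated correlation). With the ligand, 0 metallothionein genes passed edgeR over all genes and 6 passed adjusted over the list alone (median 0.47, 3.29e-12; adjusted p = 0.0334 with an estimated correlation). Mitochondrially encoded genes (median 0.04) and proteasome genes (-0.02) also passed camera with the ligand, each at 0.0248, and both calls were lost with an estimated correlation (0.671 each).

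Sterol synthesis genes were higher with the ligand and with the degrader. Low levels in the vehicle libraries alone are argued against, since the median was 0.42 for ligand against enzalutamide, with 24 of 25 genes above 0, and a gene length trend is too. The trend was at most 0.01 in size at these genes with the ligand, where its removal took the median from 0.45 to 0.44, and at most 0.06 with the degrader (1.29 to 1.28). Across the 25 genes, fold changes of the ligand against enzalutamide and of the degrader against vehicle, which share no library, had r = 0.92 (permutation p = 1e-05, the smallest these permutations can give). The permutations shuffled genes, which are not independent replicates, so this p carries no spread between libraries. A candidate explanation is a single response of different size to both compounds. The r cannot tell it from separate causes that act on the same genes. Doses are not given, so a difference in dose stays open and was not tested.

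Mitotic genes were lower with the degrader (median -0.65). A gene length trend is argued against by a median of -0.68 after its removal. With the hypoxia and glycolysis list as a covariate, read as culture state, the median was -0.74. The covariate's slope comes from replicates within groups alone. This argues against a culture state only where it acts alike within and between groups. One that differs between treatments in another way stays open. A slower cell cycle that goes with the stress response may lie behind the pattern, which was not tested.

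Read-through loci gave 2 of the 8 largest falls with the degrader, yet 13.3% of 83 such loci were called against 32.7% of all genes. Their median coefficient of variation within groups was 2.88 times that of matched genes (30.5% and 10.6%), above 100% of matched sets. An unsteady split of reads between overlapping genes may therefore explain their large fold changes. Whether the component genes changed cannot be told apart from this, since 8 of 11 called loci had the sign of their components' mean, too few to decide. With the degrader SENP3 was at -0.10 (0.19) and EIF4A1 at -0.32, the sign of SENP3-EIF4A1, while BCL2L2 was at 0.32 (5.14e-05) and PABPN1 at 0.09 (0.222), opposite to BCL2L2-PABPN1 (-1.12).

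For each comparison the 10 splits of 6 libraries are too few for a share under 0.05. For degrader against vehicle 1 split, the real one, gave as many genes (5862, highest other 1); likewise 1 for enzalutamide against vehicle (287, highest other 3), 1 for degrader against enzalutamide (6179, highest other 0) and 1 for degrader against ligand (4111, highest other 1). For ligand against vehicle 2 splits gave as many as the real 25, and the other one gave 1471. It set vehicle replicate 1 and ligand replicates 1 and 2 against vehicle replicates 2 and 3 and ligand replicate 3, which points to a structure of the samples across these groups; the next split gave 2. This structure was not tied to a known batch. The split also sorted the libraries by depth. Vehicle replicate 1 and ligand replicates 1 and 2 had 74.8, 70.8 and 71.8 M counted reads. Vehicle replicates 2 and 3 and ligand replicate 3 had 62.7, 60.2 and 55.5 M. Whether depth gave this structure was not tested.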
